A study of Bos taurus with 72 samples.

How the data were processed

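Whole blood from 24 male beef cattle was sampled at 3 stages, named entry, pulled and close-out in the labels, which gave 72 libraries. Per the labels' protocols, RNA was taken from PAXgene tubes, samples under a minimum RNA integrity were left out, and poly-A selected libraries were made with a TruSeq kit. Per the submitters' processing notes, TopHat2, HTSeq and the genome build UMD3.1 were used; their versions, the annotation release and the strand setting of the counting are not given in the sources used here. The values are the read counts per Ensembl gene as deposited by the authors, 1 column per library, with no normalization. The number of columns that matched no sample was 0. The table held 24616 genes, of which 4766 had no count in any library. Total counts per library, in megareads (M), ran from 8.24 M to 29.1 M, with a median of 17.2 M.

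The files do not pair the gene identifiers with names. Of the 24616 identifiers, 0 matched the gene table of the assembly ARS-UCD2.0 that was at hand, and that table holds another build than the counts. Genes are therefore given by identifier, and only 2 that rose and 2 that fell are printed. For the same reason the 24 gene lists fixed before the data were examined, the list scores per animal, their spread between animals, the relations between list scores across animals and the share of counts in haemoglobin genes were not computed. Reads shared between near-identical genes, or between overlapping genes on opposite strands, cannot be traced from these counts.

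Counts were analysed in R 4.3.3. Genes were kept by the edgeR 4.0.16 filter for the 3 stages, which left 12655 genes, and libraries were scaled by TMM. One quasi-likelihood model with the animal as a block and the stage as the factor was fitted to all 72 libraries. Stages were compared in that model with Benjamini-Hochberg adjustment at 0.05. The pairing comes from the animal number in the labels. Log2 CPM values used a prior count of 2. The 4 printed genes were chosen from pulled against entry by a rule fixed before the data were examined, without its condition that the gene has a symbol. The rule took genes past the adjusted p, with a mean log2 CPM of at least 1 and the same direction in at least 20 of the 24 animals, and ranked them by log2 fold change. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Library measures were compared with two-sided sign-flip permutation tests over the 24 animals with 100000 resamples.

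Libraries were compared pair by pair with a chi-square of their counts per degree of freedom. It used genes with a mean count of at least 100 per library and a summed count of at least 20 in the pair. Library identity was checked with the 100 genes whose differences between animals repeated best over the 3 stages, chosen without animals 9 and 12. The lowest repeat correlation of those genes was 0.814. This check, the division of the animals by the number in their library titles, the signature scores and the spread test were chosen after the data were examined. In the signature scores, the 100 genes per direction with the smallest p were taken from a fit without the animal that was then scored. The score was the mean log2 CPM of the genes that rose minus that of the genes that fell. The spread test was a Pitman-Morgan test on ranks.

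On simulated counts for the 12655 genes, the edgeR model for pulled against entry recovered 64% of 100 genes changed 1.5-fold and 91% of 100 genes changed 2-fold, with 5 false calls among 160. Each gene was drawn independently, with no structure shared between genes and no mislabelled library. The false calls therefore do not describe error control in the real counts, where relabelled stages gave up to 3068 genes in 1 direction in limma-voom. For a pulled against entry change that differs between 6 and 18 animals, the edgeR recovery was 4% at 1.5-fold and 33% at 2-fold. The simulated noise came from the model without a difference between these sets, so recovery in the real test may differ. The rank test of spread recovered 66.5% of 200 genes given a 2.5-fold wider spread.

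Alternatives planned before the data were examined were a fit with no block, RLE scaling, library totals only, DESeq2 1.42.0, limma-voom (limma 3.58.1), no low-count filter, at least 1 CPM in 24 libraries, only the libraries of the 2 stages compared, a test against a 1.5-fold change, an adjusted p of 0.01 and leaving out each animal. Fits without the libraries labelled pulled of animals 9 and 12, and fits within sets of animals, were added later.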

Results

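Blood transcriptomes of the same 24 cattle were measured at entry to the feedlot, when the animals were pulled, and at close-out, with 24 libraries per stage. The series title gives molecular patterns of bovine respiratory disease as its subject. The labels do not record a diagnosis per animal, a pathogen or the days between samplings, and no healthy animals sampled at matched times were analysed here. Stage therefore also carries age and time on feed. Mean total counts, in megareads (M), were 17.8 ± 4.36 M at entry, 17.0 ± 3.87 M at pulled and 17.2 ± 4.28 M at close-out (SD, n = 24). Totals did not differ past the threshold between pulled and entry (permutation test, adjusted p = 0.698 over 15 tests). Slightly fewer genes had a count at pulled (15101 ± 327, SD, n = 24) than at close-out (15353 ± 259), with 18 of 24 animals higher at close-out (adjusted p = 0.0249, two-sided sign-flip permutation test). The TMM factor was also lower at pulled (0.939 ± 0.0954) than at close-out (1.04 ± 0.155, SD, n = 24), with 20 of 24 animals higher at close-out (permutation test, adjusted p = 0.021).

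The entry libraries fell into separate sets. The first principal component held 38.8% of the variance of log2 CPM. At entry, the 6 animals with the highest numbers in their library titles (from 108 up) scored 33.9 or more. The other 18 animals, with numbers up to 98, scored from -92.6 to 0.519. At pulled and close-out the scores of both sets overlapped. Both sets shifted after entry. The mean score of the 18 was -47.9 at entry, 20.4 at pulled and 8.46 at close-out. For the 6 it was 66.7, -8.33 and -1.22. Neither set is therefore taken as the reference. This division was noticed in the principal components and is not a group of the study. Comparisons with entry are given below for all animals and within each set.

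**Figure D1:**
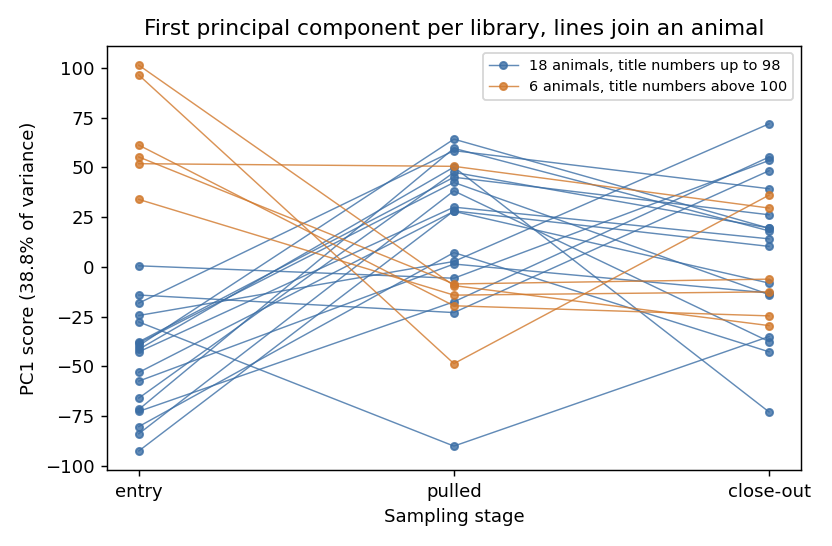
Score of each library on the first principal component (vertical axis, no unit) by sampling stage (horizontal axis), with lines joining the 3 libraries of an animal. The 6 animals with title numbers above 100 lie at 33.9 or more at entry, and the other 18 at -92.6 to 0.519.

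The labels of 2 pulled libraries did not match the rest of their animal. Over the 100 identity genes, 68 same-animal pairs among the other 70 libraries had correlations of at least 0.799 (median 0.925), and 2347 pairs of different animals reached at most 0.457 (across genes, which are not independent replicates). Most of these libraries also served to choose the genes, which favours high same-animal values. With 100 genes chosen on the other stages only, each of the 70 libraries matched its own animal best, at 0.643 or more. With 300 such genes the lowest value was 0.354, and entry of animal 11 matched animal 9 (0.683) above its own animal (0.584). Here each library was compared with the mean of an animal's other 2 stages. The value of 0.683 for animal 9 therefore includes the doubted library labelled pulled of animal 9. The library labelled pulled of animal 9 correlated at -0.0496 with entry and -0.059 with close-out of animal 9. It correlated at 0.955 with entry of animal 11. The library labelled pulled of animal 12 correlated at 0.053 with entry and 0.0239 with close-out of animal 12. Both libraries were kept under their labels, and counts without them are given.

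For pulled against entry, 4 genes are given. ENSBTAG00000046158 and ENSBTAG00000006999 rose, and ENSBTAG00000011824 and ENSBTAG00000043582 fell. ENSBTAG00000046158 had a mean log2 CPM of 3.12 ± 1.46 at entry and 5.92 ± 1.72 at pulled (SD, n = 24), a log2 fold change of 2.91 (SE 0.43, edgeR adjusted p = 3.28e-06) with 20 of 24 animals higher. ENSBTAG00000006999 went from 3.24 ± 1.82 to 5.48 ± 1.64, a log2 fold change of 2.44 (SE 0.56, edgeR adjusted p = 0.000771), also higher in 20 animals. ENSBTAG00000011824 went from 2.67 ± 1.32 to 0.38 ± 1.33, a log2 fold change of -2.47 (SE 0.39, edgeR adjusted p = 7.97e-06), lower in 22 of 24 animals. Its counts at pulled ran from 1 to 184. ENSBTAG00000043582 went from 5.45 ± 0.59 to 3.18 ± 1.49, a log2 fold change of -2.21 (SE 0.36, edgeR adjusted p = 1.09e-05), lower in 21 animals. Animals 9 and 12, whose pulled libraries are doubted, are in these counts of animals. Without them, ENSBTAG00000046158, ENSBTAG00000006999 and ENSBTAG00000043582 would not reach the 20 animals of the rule. With those pulled libraries left out, the log2 fold changes of the 4 genes, in the order above, were 2.75, 2.19, -2.62 and -2.23 (edgeR adjusted p of 0.00249 or less). Of these 4 genes, ENSBTAG00000006999 and ENSBTAG00000011824 did not pass within the 6 animals with title numbers above 100, where their log2 fold changes were 1.90 and -0.06.

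**Figure D2:**
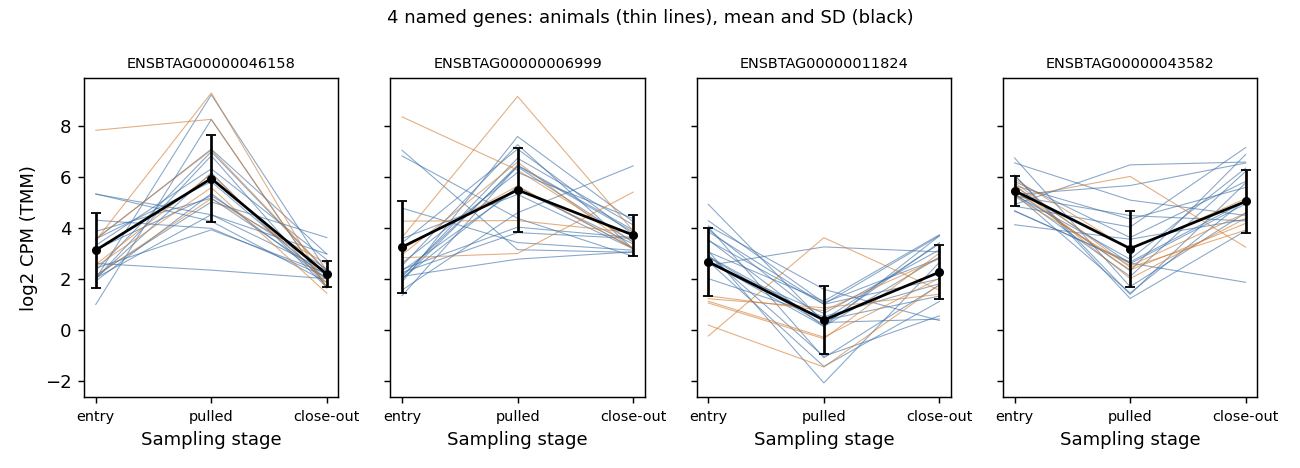
Log2 CPM (vertical axis, TMM scaled) of 4 genes at the 3 stages (horizontal axis). Thin lines are animals, blue for the 18 with title numbers up to 98 and orange for the 6 above 100; black points and bars are the mean and SD of 24 animals. The mean of ENSBTAG00000046158 goes from 3.12 to 5.92 and then 2.18.

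Over all genes, 2552 were higher and 2768 lower at pulled than at entry among 12655 tested (edgeR, adjusted p under 0.05). Most changes were small. The median log2 fold change was 0.42 among the higher and -0.58 among the lower genes, and 153 and 335 genes passed with more than a 2-fold change. Only 52 higher and 34 lower genes passed a test against a 1.5-fold change. With library totals only in place of TMM, the share of lower genes among those past the threshold went from 52.0% to 74.4%, while the median log2 fold change of all genes moved from -0.03 to -0.19.

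These counts did not hold alike in both sets of animals. Within the 18 animals 4285 genes were higher and 4667 lower at pulled, and within the 6 animals 2697 were higher and 2446 lower. Of the genes past the threshold in both sets, 103 were higher in both, 103 lower in both and 3806 went in opposite directions. Independent lists of these lengths would share 913 and 902 genes. The fold changes of both sets correlated at -0.578 across 12655 genes, which are not independent replicates. Of the 5320 genes past the threshold over all animals, 5050 passed in the same direction within the 18 animals, 367 within the 6, and 1250 passed in the opposite direction within the 6.

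**Figure D3:**
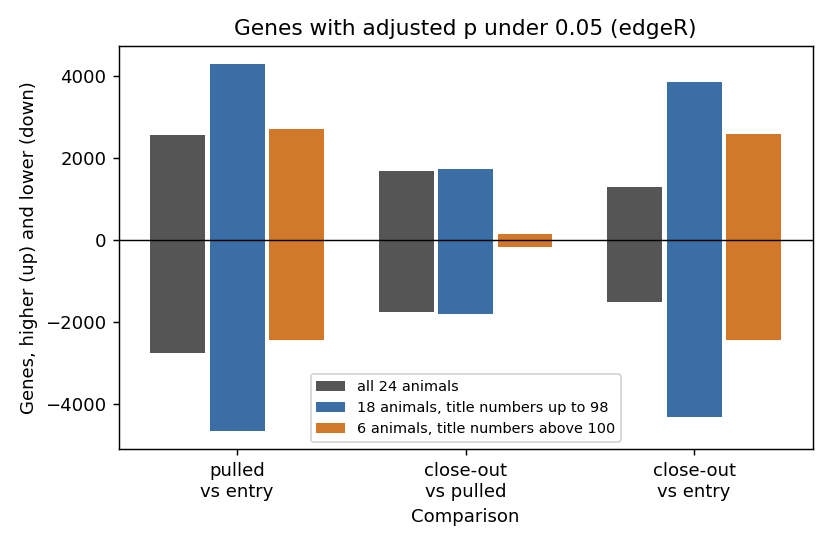
Number of genes past an adjusted p of 0.05 in edgeR (vertical axis), higher above 0 and lower drawn below 0, for each comparison (horizontal axis), in all 24 animals, the 18 and the 6. Close-out against pulled has 1717 higher genes in the 18 animals and 145 in the 6, while pulled against entry has 4285 and 2697.

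Close-out against pulled does not set a stage against entry, but the entry libraries entered the shared estimate of the spread. The 4 genes were chosen for large changes at pulled, and both comparisons share the pulled libraries. Part of their return at close-out may therefore follow from that choice. ENSBTAG00000046158 fell to 2.18 ± 0.52 at close-out (SD, n = 24), a log2 fold change of -3.96 (SE 0.43, edgeR adjusted p = 1.06e-09), lower in 24 of 24 animals. ENSBTAG00000006999 fell by 2.07 on the log2 scale (SE 0.50, edgeR adjusted p = 0.0014), lower in 21 animals. ENSBTAG00000011824 rose with a log2 fold change of 1.97 (SE 0.38, edgeR adjusted p = 8.66e-05), higher in 21 animals. ENSBTAG00000043582 rose with a log2 fold change of 1.79 (SE 0.35, edgeR adjusted p = 0.000116), higher in 20 animals. Within the 6 animals ENSBTAG00000006999, ENSBTAG00000011824 and ENSBTAG00000043582 did not pass, with log2 fold changes of -2.25, 1.39 and 1.15 (edgeR adjusted p = 0.345, 0.364 and 0.39). In total 1681 genes were higher and 1765 lower at close-out (edgeR), and the largest fall was -4.71 on the log2 scale. There were 52 genes lower and 38 higher in every one of the 24 animals. All counts of animals here include animals 9 and 12, whose pulled libraries are doubted. Only 126 higher and 190 lower genes passed a test against a 1.5-fold change. With only the libraries of the 2 stages fitted, 2150 genes were higher and 1828 lower at close-out.

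Within the 18 animals 1717 genes were higher and 1821 lower at close-out than at pulled, and within the 6 animals 145 and 174. The fold changes of both sets correlated at 0.808 across genes. Of the genes past the threshold in both sets, 133 were higher and 164 lower in both, and 0 went in opposite directions, with 19.7 and 25.0 expected of independent lists. A test of the difference between the sets found 0 genes in edgeR and 0 in limma-voom (261 and 247 at an unadjusted p under 0.05). Those unadjusted counts are below the number expected with no difference. On simulated counts such an edgeR test for pulled against entry recovered 4% of genes at 1.5-fold and 33% at 2-fold, so differences may have been missed. Recovery for close-out against pulled was not simulated. With library totals only, the share of higher genes went from 48.8% to 76.2%, and the median log2 fold change of all genes from -0.01 to 0.13.

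At close-out 1295 genes were higher and 1517 lower than at entry (edgeR). The lower count was 971 without animal 20 and 2528 without animal 2. None of the 4 genes passed in this model, while ENSBTAG00000046158 passed under 12 and ENSBTAG00000011824 under 2 of the alternatives. ENSBTAG00000046158 had a log2 fold change of -1.05 (SE 0.40, edgeR adjusted p = 0.0528), and ENSBTAG00000006999 one of 0.37 (SE 0.52, adjusted p = 0.62). ENSBTAG00000011824 had -0.50 (SE 0.36, edgeR adjusted p = 0.305) and ENSBTAG00000043582 -0.41 (SE 0.33, adjusted p = 0.356). Within the 18 animals 3853 genes were higher and 4325 lower, and within the 6 animals 2590 and 2439. Of the genes past the threshold in both sets, 164 were higher in both, 110 lower in both and 3592 opposite, and the fold changes correlated at -0.502 across genes. Only 59 higher and 72 lower genes passed a test against a 1.5-fold change. With library totals only, the share of higher genes went from 46.1% to 58.3%.

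Genes that stood out at pulled were taken as those past the threshold against both other stages. There were 1079 such genes higher at pulled and 923 lower (edgeR). With library totals only they were 515 and 1700, and against a 1.5-fold change 27 and 17. Independent lists of the same lengths would share 356 and 368 genes, and relabelling the stages within animals gave a median of 0 in limma-voom. Both comparisons share the pulled libraries. When each was fitted on a separate 12 animals in limma-voom, the median over 20 divisions was 173 genes higher (51 to 447) and 149 lower (25 to 331). Independent lists gave medians of 48.4 and 41.2, and 20 and 19 of the 20 divisions were above their own such value. Within the 6 animals the genes past both comparisons in edgeR were 94 higher and 83 lower at pulled. Of the 1079 genes higher at pulled, 953 did not differ past the threshold between close-out and entry in the fit of all animals. For close-out against entry, 3592 genes past the threshold in both sets of animals went in opposite directions. Opposite changes can cancel in the fit of all animals, so the 953 genes are not shown to have returned to their entry level. How many of them changed within a set was not tested.

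Scores of genes chosen without the animal scored showed how alike the animals were. The close-out against pulled score rose in 24 of 24 animals, by 2.91 ± 0.97 (SD, n = 24, log2 units). The pulled against entry score rose in 22 of 24 animals, by 1.42 ± 1.05. Animal 9, whose pulled library is doubted, was among those that fell. With animals 9 and 12 not scored, it rose in 21 of 22 (1.43 ± 0.95) and the close-out against pulled score in 22 of 22 (2.88 ± 0.96). The library labelled pulled of animal 9, which matched entry of animal 11, stayed in the fit that left out animal 11. Genes for animal 11 were therefore not chosen wholly without its RNA. In the 18 animals the pulled against entry rise was 1.81 ± 0.83, and in the 6 it was 0.26 ± 0.74 with 5 of 6 higher. With 50 genes per direction these rises were 1.79 and 0.36, and with 200 genes 1.65 and 0.13. The close-out against entry score rose in 24 of 24 animals, by 2.23 ± 0.76, with 2.47 ± 0.60 in the 18 and 1.53 ± 0.81 in the 6. Genes with the smallest p over all animals favour those that move alike in both sets.

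**Figure D4:**
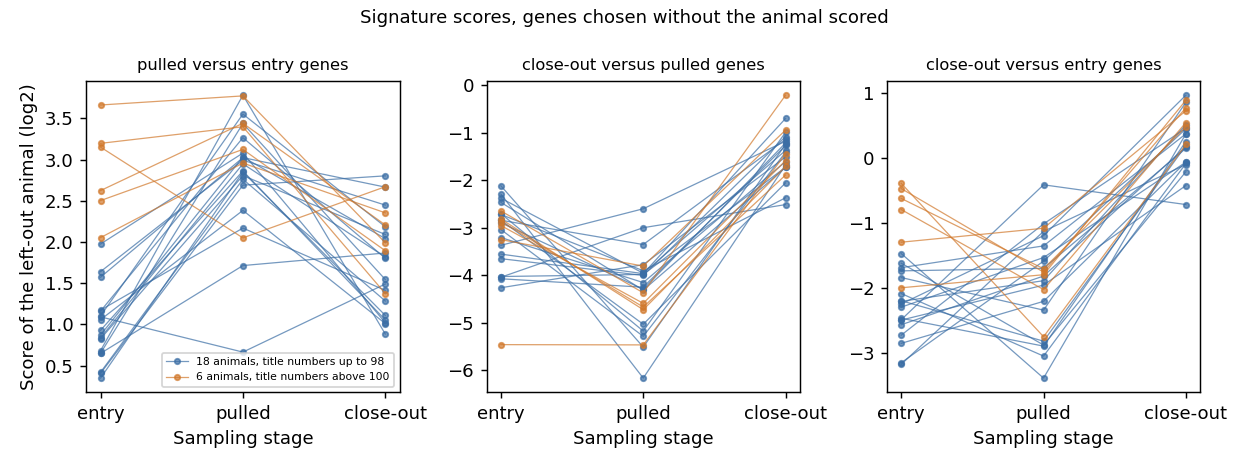
Score of each left-out animal (vertical axis, mean log2 CPM of genes that rose minus genes that fell, 100 genes per direction) at the 3 stages (horizontal axis), for the genes of each comparison. Blue lines are the 18 animals with title numbers up to 98 and orange lines the 6 above 100; the close-out against pulled score rises in 24 of 24 animals.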

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

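All tests in this part except the thinning to equal depth were chosen, or their outcome partly known, after the results they bear on had been seen.

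The change from entry to pulled differed between the 6 animals with title numbers above 100 and the other 18 in 8651 genes, and the change from entry to close-out in 8174 genes (edgeR, test of the difference). The division was chosen because the sets stood apart at entry, so these counts describe it and are not independent evidence for it. In limma-voom the counts were 8676 and 8181. Among 100 sets of 6 animals, the real one included, 1 gave as many genes for each, and the highest of the others was 1 gene; this does not test chance, since the set was chosen from the same libraries. For close-out minus pulled the count was 0, as in all 100 sets (edgeR, 261 genes at an unadjusted p under 0.05; limma-voom 0 and 247). Of the 18 other divisions in the order of title numbers, 8 gave 0 genes for pulled minus entry and 11 gave 0 for close-out minus entry (limma-voom), and the highest counts were 7938 and 7834.

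Exchanged entry and pulled labels in the 6 animals would make their close-out minus pulled change resemble the close-out minus entry change of the 18. Instead it correlated at 0.803 with close-out minus pulled of the 18 and at 0.377 with close-out minus entry (limma-voom), and the order held without each of the 6 animals in turn. Other values go with an exchange: close-out minus entry of the 6 correlated at 0.506 with close-out minus pulled of the 18 and at -0.502 with close-out minus entry (edgeR). An exchange would also set entry libraries of the 6 among the pulled libraries of the 18, where the sets differed in 0 genes (limma-voom, 2157 at an unadjusted p under 0.05), against 8996 at entry. Library depth is argued against too, since 8278 genes still differed after every library was thinned to 8.24 M reads. At close-out the sets differed in 5 genes (limma-voom). At entry the 6 libraries also had a TMM factor of 0.806 ± 0.0966 (SD, n = 6) against 1.14 ± 0.0876 (n = 18), 14913 ± 213 against 15579 ± 335 genes with a count, and 8.44% ± 1.17 against 7.52% ± 0.767 of counts in the 10 most abundant genes. A library batch at entry and a different state of the animals at arrival cannot be told apart because the labels give no batch or date. Both remain open, and either could lie in the 6 animals, in the 18 or in both.

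The library labelled pulled of animal 9 and the entry library of animal 11 differed by a chi-square per degree of freedom of 1.46, where sampling noise alone gives about 1, while the next lowest of 2556 pairs was 29.1. Different animals in a like state are argued against by the correlation of 0.955 over identity genes, above the highest value of 0.457 between different animals among the other 70 libraries. RNA of animal 11 under the label of animal 9 is a candidate explanation, since the correlations with all 3 libraries of animal 11 were at least 0.888. The near-identity was with its entry library, and every other pair, those of animal 11 included, was at 29.1 or more, which points to the entry sample.

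The library labelled pulled of animal 12 matched no animal. Low depth is argued against, because 34 libraries with fewer counts than its 17.2 M reads matched their own animal at 0.827 or more; the library labelled pulled of animal 9, also smaller, was left out of that count. Most of those libraries also served to choose the genes. With genes chosen on the other stages only, the lowest own value of the 70 libraries was 0.643 with 100 genes and 0.354 with 300. For the library labelled pulled of animal 12 the values were -0.0407 and 0.0299. The 0.643 belongs to close-out of animal 12, whose comparison averaged in this doubted library (0.158 with it, 0.874 with entry of animal 12). An exchange with another animal of the series is argued against by a highest correlation of 0.189 with any other library, under the lowest same-animal value of 0.799. With genes chosen on the other stages the highest was 0.161 with 100 genes and 0.124 with 300, under 0.643 and 0.354. RNA from an animal outside the series may also give 0.189, but cannot be told apart from other sources because no outside library was analysed here. No biological explanation was tested.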

How the results depend on the processing

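Fits within sets of animals and without doubted libraries were chosen after the data were examined; the causes of the shifts below were not tested unless stated. Counts are given as higher and lower for pulled against entry, close-out against pulled, close-out against entry, and pulled against both, where they moved by over 1.5 times. With library totals only they were 1565 and 4539, 2786 and 872, and 515 and 1700 for pulled against both. At an adjusted p of 0.01 they were 1559 and 1508, 1010 and 1037, 727 and 528, and 527 and 455. Against a 1.5-fold change they were 52 and 34, 126 and 190, 59 and 72, and 27 and 17. With only the 2 stages compared, 1723 genes were lower at pulled than at entry. In the 18 animals the counts were 4285 and 4667 for pulled against entry and 3853 and 4325 for close-out against entry. In the 6 animals they were 145 and 174 for close-out against pulled, 2590 and 2439 for close-out against entry, and 94 and 83 for pulled against both, with fewer samples. In the 18 animals without the libraries labelled pulled of animals 9 and 12 they were 4404 and 4769, 3973 and 4389, and 1724 and 1473 for pulled against both.

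Without the libraries labelled pulled of animals 9 and 12 in all animals, the 8 counts stayed within 1.5 times (2622 and 2820, 1621 and 1751, 1349 and 1510, 1096 and 936). Leaving out each animal gave 971 to 2528 genes lower at close-out than at entry, the lowest without animal 20 and the highest without animal 2. The other 7 counts stayed within 1.5 times under each omission. With no replicate block the counts were 2119 and 2643, 1371 and 1584, 972 and 1460, and 842 and 741, so dropping the pairing moved none by over 1.5 times. RLE, DESeq2, limma-voom and both other filters also moved none of the 8 counts by that much. Without the block, fold changes of single genes did shift. ENSBTAG00000046158 in close-out against entry went from -1.05 (edgeR adjusted p = 0.0528) to -2.01 (edgeR adjusted p = 0.000976). In pulled against entry, ENSBTAG00000006999 went from 2.44 to 1.43 and ENSBTAG00000011824 from -2.47 to -2.14.

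The 4 genes kept their direction in pulled against entry and close-out against pulled under all 37 alternatives each, and 5 of these 8 results lost their call in the 6 animals and under no other alternative. There ENSBTAG00000011824 had a pulled against entry value of -0.06 (edgeR adjusted p = 0.953), against -2.47 in all animals. For close-out against entry, which did not pass, ENSBTAG00000006999 turned to -0.91 without the block and -0.35 in the 6 animals, and ENSBTAG00000011824 to 1.33 in the 6 animals. Removal of haemoglobin genes and all gene list alternatives were not run, since no identifier could be matched to a name.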

Other observations

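The signature scores, spread test and random sets of animals were added after the data were examined; the relabelling of stages was planned.

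Stages were relabelled within animals in limma-voom, with 100 labellings including the real one. For pulled against entry, 1 of 100 gave as many genes as the real 2707 higher and 2767 lower, and the highest of the others were 2407 and 2641. For close-out against pulled, 2 of 100 gave as many as 1773 higher and 1694 lower, and the highest others were 3068 and 2448. For close-out against entry, 1 of 100 reached 1407 higher and 1226 lower, with highest others of 154 and 94. For pulled against both, 1 of 100 reached 1065 higher and 974 lower, and the highest others were 0 and 0. The share was under 0.05 for each of these 8 counts, with no adjustment over the 8, so random labellings seldom gave as many genes. Some relabellings still gave high counts. Whether those followed the true stages, the division of the animals or another structure of the samples was not tested.

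A hypothesis that animals differ more from each other when pulled was tested as spread. In 228 genes the spread between animals was wider at pulled than at close-out and in 0 it was narrower (rank test). At an unadjusted p under 0.05 these were 1763 and 87, and the test on values gave 286 and 5 past the threshold. The median SD ratio was 2.16 among those 228 genes, which were chosen for a wider spread at pulled. Over all genes the median log2 SD ratio of close-out to pulled was -0.205. It was -0.118 without animals 9 and 12 and -0.0917 in the 18 animals. Swapping the stages within animals gave at most 4 genes, and 1 of 100 swaps, the real one included, gave as many. Against entry the direction depended on the animals. Over 24 animals 1 gene was wider at pulled and 0 at entry (rank test; 483 and 870 at an unadjusted p under 0.05; 7 and 3 in the test on values), and without animals 9 and 12 the counts were 14 and 150 (94 and 959 on values). In the 18 animals they were 0 and 0 (1490 and 49 at an unadjusted p under 0.05; 0 and 0 on values), with 84.6% of genes wider at pulled against 40.0% over 24 animals. Entry was also wider than close-out over 24 animals, in 74 genes against 8 (743 and 38 on values), but narrower in the 18 animals (14 against 305, or 7 and 92 on values), so a narrow spread at close-out is not separated from a wide one at pulled. The count of pulled against close-out was 92 without animals 9 and 12 and 14 in the 18 animals, so it rests in part on the doubted libraries and on which animals enter, and may not reflect the animals alone. Of the 228 genes, 92 were also lower at close-out and 27 higher.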
